A study of Danio rerio with 8 samples.

How the data were processed

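Gene expression was measured by total RNA sequencing of livers dissected from zebrafish larvae at 7 days of age. Each library was made from a pool of 10 livers, and there were 4 libraries from wild-type (WT) larvae and 4 from larvae of the transgenic line lf:YAP, in which YAP is activated in hepatocytes, per the labels. Per the labels' protocols, RNA was taken up in TRIzol and purified on columns, libraries were made with a stranded total RNA kit for very small inputs, and sequencing on a NextSeq instrument used paired 75-base reads with a stated depth of 15M reads per sample. Larvae were raised in plates from day 3, with no treatment. The labels do not say whether the pools came from separate clutches, so the p-values measure only the spread between these pools, which may in part be technical.

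Per the submitters' processing notes, cutadapt 1.16, HISAT2 2.1.0, featureCounts 1.6.0, limma 3.40.6 and the genome build danRer10 were used, with no role or order stated; the annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical paralogs may have been split between them or left out. The authors deposited 1 table with a whole-number count per gene and library, not normalized, and a CPM value per gene and library, which equals the count divided by the column total and scaled to 1e6. The authors' deposited table also holds a log2 fold change of lf:YAP over WT, a mean log2 expression, a p-value and an adjusted p-value per gene, per the file headers and the values; the test behind them is known only from the naming of limma in the processing notes. All results below were computed from the deposited counts, and the authors' values were used only for a comparison of calls. Every count column belonged to 1 library of the series.

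The table has 35117 rows, of which 6518 carry no gene name. Those rows held 0.657% to 2.55% of the counts of a library and were left out of library sizes and tests. The table has gene symbols and no gene identifiers or coordinates, and no genome was used here, so genes are given by symbol alone; the symbols of 5 listed genes were matched by hand to the name in the table, with the RefSeq gene table of the assembly GRCz12tu as a guide. For 405 symbols on more than 1 row, a gene list used the row with the highest total count. Another 18 names had been turned into dates by spreadsheet software and were not used as gene names.

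Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as its factor, libraries were scaled by TMM factors, and lf:YAP was compared with WT by the robust quasi-likelihood F-test, 2-sided, with an intercept and the group as the only terms. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called changed. The standard error (SE) of a log2 fold change is approximate, being its size divided by the square root of F. Levels are TMM-scaled CPM, as mean ± SD over the 4 libraries of a group. Intervals of a log2 fold change used a 95% level and 6 residual degrees of freedom. Where all libraries of a group had a count of 0, the fold was set against a floor of 3 counts over that group; floors and intervals from counts cover counting error only.

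Before the data were examined, 26 gene lists were fixed: 5 for the subjects of the series title (YAP/TEAD targets, cholesterol synthesis and uptake, fatty acid and triglyceride synthesis, the SGK and mTORC1 pathway, and the cell cycle), and others for Hippo components, hepatocyte function, metabolism, stress, inflammation, ribosome biogenesis, Notch, Wnt and TGF-beta signalling, and markers of other cell types that a dissected liver could hold. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, 2-sided, adjusted over the 23 such lists. Camera with an estimated correlation and fry were the alternatives. Camera compares a list with all other genes, and fry asks whether the members of a list move 1 way on balance.

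The genes named in the text were chosen by a rule fixed at the same time: yap1, wwtr1, sgk1, mtor, srebf1 and srebf2; the 10 highest and 10 lowest log2 fold changes among changed genes with a mean log2 CPM of at least 2 and no overlap between the groups, with clone names passed over (0 among the highest and 1 among the lowest); and up to 5 members of each list with the smallest p. Names outside this rule, given to complete a small count or as further examples, were chosen after their values were seen. Principal components were taken from the 500 most variable genes. Symbol families with at least 10 tested members were examined only after the data had been seen.

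The depth per library was 2668432 to 3797709 counts on named genes, but 3 rows of ribosomal and mitochondrial RNA took 50.6% to 57.1% of them, so that 1160227 to 1702876 counts measured all other genes. The test was tried on simulated counts for the same 8369 genes with the real means and library sizes, with 100 genes changed by 2-fold and 100 by 4-fold. It recovered 36% of the 2-fold and 83% of the 4-fold changes, with 9 false calls (7.03% of the calls). Far fewer genes were changed there than the 1804 called in the real data. Its adjusted threshold was therefore stricter, and these shares may understate the recovery in the real comparison. A gene that did not pass may still have changed by 2-fold. A simulated shifted list was recovered and 0 of 20 null lists were called. The simulated genes were drawn independently, so this could not show false list calls that come from correlated members. In the real data the estimated correlation ran from -0.016 for the nucleotide and glutamine list to 0.948 for the exocrine pancreas list.

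The other analyses chosen at the outset were RLE and upper quartile factors, total counts alone, removal of the 20 most abundant genes, no count filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a glmTreat test against a 1.5-fold change, and marker genes left out of the counts. The filter of at least 1 CPM had been meant as a stricter one but kept 12875 genes, more than the main filter. Added after the data had been seen were a fit with the unnamed rows, a fit without the 2 libraries richest in pancreatic counts, a fit with the exocrine pancreas mean as a covariate, and the macrophage list under the other filters with each library left out or an estimated correlation, and the exocrine list with an estimated correlation and each library left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Some members of the lists, counted among those tested, are not reported here by name.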

Results

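Total RNA was sequenced from pools of 10 livers of zebrafish larvae at 7 days of age, with 4 pools from WT larvae and 4 from the lf:YAP line, whose hepatocytes carry active YAP, the transcriptional effector of the Hippo pathway. The comparison addresses which transcripts differ when YAP is active in hepatocytes, and, from the subjects of the series title, the genes of SGK1 and mTORC1 signalling, SREBP-dependent lipid synthesis and proliferation. The libraries held 2853543 to 3797709 counts on named genes in WT and 2668432 to 3170508 in lf:YAP, with means of 3115188 ± 455984 and 2902999 ± 254589 (SD, n = 4 each), a difference that did not pass a 2-sided exact permutation test (p = 0.571). A single ribosomal RNA row took 26.4 ± 8.02% of the counts in WT and 30.3 ± 1.25% in lf:YAP (SD, n = 4 each).

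The libraries separated by group along the main axis of variation. The first principal component held 78.0% of the variance, with WT libraries between -25.4 and -21.1 and lf:YAP libraries at 19.2, 32.4, 6.28 and 37.7 for replicates 1 to 4. The lf:YAP library nearest to WT, replicate 3, also had the highest share of exocrine pancreas transcripts, 1.48% of its counts against 0.409% to 0.480% in the other lf:YAP libraries. Of the WT libraries, replicate 4 had the highest such share, 1.26%.

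**Figure D1:**
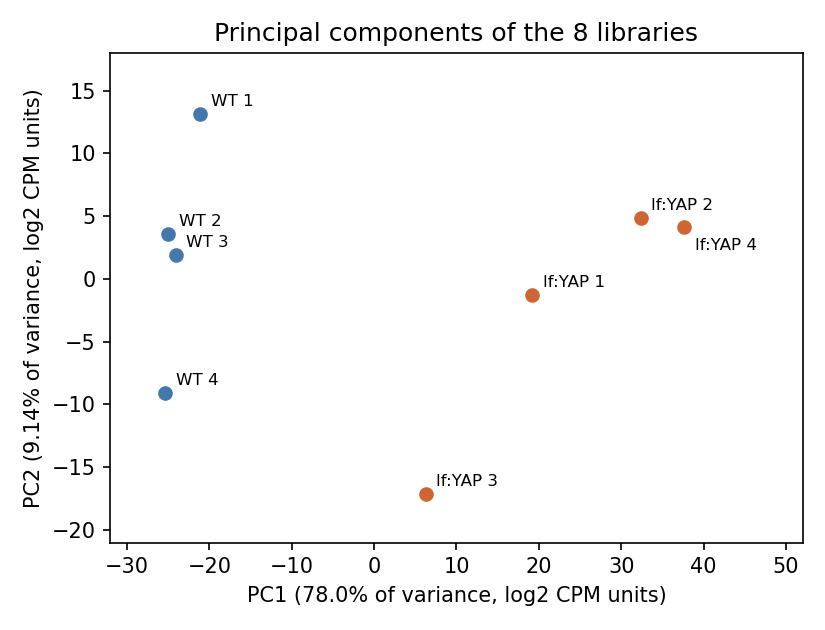
Principal components of log2 CPM of the 500 most variable genes, with the first component (78.0% of the variance) on the x axis and the second (9.14%) on the y axis, and 1 point per library (blue WT, orange lf:YAP). The 4 WT libraries lie between -25.4 and -21.1 on the first component, and lf:YAP replicate 3, at 6.28, is the lf:YAP library closest to them.

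The yap1 transcript was 38.2-fold higher in lf:YAP livers. Its level was 21.5 ± 3.34 CPM in WT and 822 ± 444 CPM in lf:YAP (SD, n = 4 each), a log2 fold change of 5.26 ± 0.45 (SE) with an adjusted p of 7.5e-05 by the edgeR quasi-likelihood test. The lf:YAP libraries had 639, 1025, 303 and 1320 CPM for replicates 1 to 4, each above all WT libraries. The labels do not say which yap1 sequence the transgene carries, so the share of transgene reads in this row is unknown. The paralog wwtr1, which encodes TAZ, had a log2 fold change of 0.20 ± 0.24 (adjusted p = 0.591).

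Across the transcriptome, 1804 of 8369 genes tested were changed, with 929 higher and 875 lower in lf:YAP. At least 2-fold changes were found for 553 of the higher and 540 of the lower genes. At an unadjusted p under 0.05 there were 2911 genes, and the groups did not overlap at all for 1985 genes, 23.7% of those tested against 2.86% by chance. With libraries scaled by total counts alone, the median log2 fold change of all genes moved from 0.01 to 0.32, and the split became 1537 higher and 517 lower, so the balance of higher against lower genes is relative to the scaling. In the authors' deposited table, 1762 rows had an adjusted p under 0.05, with 894 higher and 868 lower. Of the tested genes, 1227 were called by both, all in the same direction; 577 were called here alone and 23 in the authors' deposited table alone.

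The largest increases included that of the nuclear lamin gene lmna, which reached 85.2 ± 29.9 CPM in lf:YAP (SD, n = 4), a log2 fold change of 5.30 ± 0.37 (SE). The inducible nitric oxide synthase gene nos2a rose from 0.359 ± 0.320 to 46.6 ± 36.4 CPM, a log2 fold change of 6.89 ± 0.91, and 6.23 without lf:YAP replicate 2. notum2, of the family of secreted Wnt-inactivating carboxylesterases, had a count of 0 in all 4 WT libraries and 22.1 ± 13.9 CPM in lf:YAP, at least 82.6-fold higher against a floor of 3 counts over the WT group. The glucose transporter family gene slc5a9, the kinase gene btk and the sulfotransferase gene chst6 rose by 5.11, 5.01 and 4.65 on the log2 scale. The kinase gene prkacba had 2 counts in WT and 145 in lf:YAP, a ratio of 62.7 with a counting interval of 17.1 to 522.6; both WT counts were in replicate 4, without which its log2 fold change moved from 5.70 to 8.05. Adjusted p-values in this group lay at or below 0.0104.

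The largest decreases included channel, enzyme and adhesion genes. The water and glycerol channel gene aqp10a fell from 68.5 ± 11.1 to 4.81 ± 2.66 CPM (SD, n = 4 each), a log2 fold change of -3.91 ± 0.32 (SE; adjusted p = 3e-05). The catechol methyltransferase family gene comtd1 had a log2 fold change of -4.95 ± 0.46, and -5.83 without lf:YAP replicate 3. The sulfotransferase gene sult3st2 had -3.63 ± 0.45, and the hepatic transcription factor family gene onecutl had -3.80 ± 0.38. The cell adhesion gene dscama (-4.28), the calcineurin regulator rcan2 (-4.06), arhgap32a (-3.79), the glycosyltransferase gene mgat4b (-3.79) and the immediate early gene egr3 (-3.76) were lower. The cytochrome P450 gene cyp2aa8 had 79 counts in WT and 1 in lf:YAP, a ratio of 91.4 with a counting interval of 15.9 to 3653; without lf:YAP replicate 1, which held that count, its log2 fold change moved from -5.90 to -7.44.

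Target genes of YAP and its TEAD partners rose in lf:YAP livers. Of 15 tested members, 10 were higher, 0 were lower and 5 did not pass, with the same 10 adjusted over the list alone, and the median log2 fold change was 1.04. The angiomotin-like genes amotl2b and amotl2a, which encode inhibitors of YAP, rose from 12.1 ± 2.79 to 269 ± 139 CPM and from 20.6 ± 4.03 to 132 ± 61.9 CPM (SD, n = 4 each). The Hippo kinase gene lats2 rose by 2.28 ± 0.23, the kinase gene nuak2 by 4.44 ± 0.47 and the matricellular gene ccn2a by 3.34 ± 0.48 on the log2 scale (± SE). Camera gave the list an adjusted p of 0.000121, but an adjusted p of 0.437 with an estimated correlation. Of 24 tested Hippo pathway components, 9 were higher and 1 was lower (12 and 1 adjusted over the list alone), with yap1 itself, lats2, amotl2a, amotl2b and the scaffold gene wwc1 (1.18 ± 0.19) leading; lats2 and both angiomotin-like genes are in both lists. That list had an adjusted p of 7.26e-05 by camera and an adjusted p of 0.437 with an estimated correlation. As it holds yap1 and the shared targets, its result is not independent of the transgene or of the target list. The Hippo list was not tested without these genes.

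**Figure D2:**
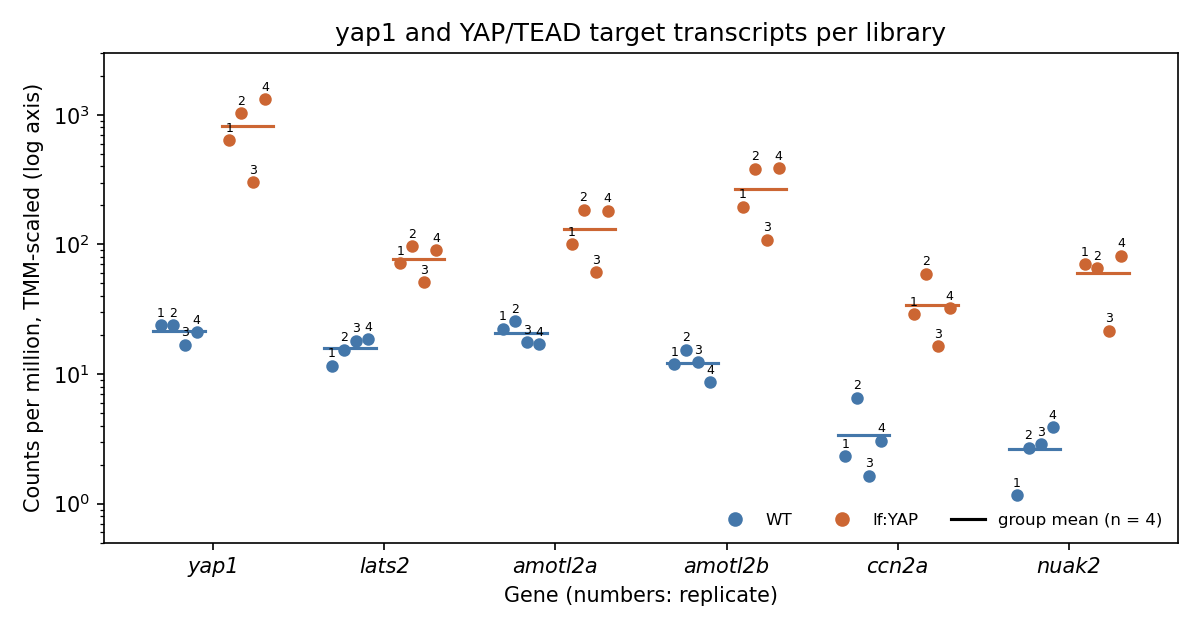
Level of yap1 and of 5 YAP/TEAD target genes in each library, in TMM-scaled CPM on a log axis, with points numbered by replicate and a line at the mean of each group (blue WT, orange lf:YAP, n = 4 each). All lf:YAP points lie above all WT points for each gene, and replicate 3 is the lowest lf:YAP library for yap1, at 303 CPM.

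Genes of cholesterol synthesis and uptake, the targets of SREBP2, were higher in lf:YAP. Of 20 tested members, 13 rose, tm7sf2 fell (-1.06 ± 0.31) and 6 did not pass; adjusted over the list alone, 14 rose and 1 fell. The sterol demethylase gene cyp51 rose from 11.2 ± 2.17 to 79.0 ± 21.0 CPM (SD, n = 4 each), with a log2 fold change of 2.83 ± 0.23 (SE; adjusted p = 1.2e-05). The farnesyl diphosphate synthase gene fdps (3.02 ± 0.42), sc5d (2.21 ± 0.36) and msmo1 (1.23 ± 0.21), all enzymes of the same pathway, also rose. The rate-limiting enzyme gene hmgcra had 2.53 ± 0.61. The transcription factor gene srebf2 rose from 41.0 ± 12.8 to 75.7 ± 17.2 CPM, a log2 fold change of 0.89 ± 0.23 (adjusted p = 0.0159). Its adjusted p was 0.0596 without WT replicate 2 and 0.0501 without WT replicate 4. The median over the list was 1.07, with an adjusted p of 7.26e-05 by camera and an adjusted p of 0.437 with an estimated correlation.

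Genes of fatty acid and triglyceride synthesis, the targets of SREBP1, moved in both directions. Of 23 tested members, 8 rose and 5 fell, and 10 rose and 8 fell adjusted over the list alone. The desaturase gene fads2 rose from 10.5 ± 2.51 to 84.4 ± 33.7 CPM (SD, n = 4 each), a log2 fold change of 3.03 ± 0.31 (SE), and aclya, encoding ATP citrate lyase, by 1.45 ± 0.20. The fatty acid synthase gene fasn (0.87 ± 0.18), the carbohydrate-response factor gene mlxipl (1.09 ± 0.23) and srebf1 itself (0.70 ± 0.15, adjusted p = 0.00657) also rose. The 5 members that fell, named after their values were seen, were the phosphatidate phosphatase gene lpin1 (-0.78), acacb (-0.69), acss2 (-0.98) and the diacylglycerol acyltransferase genes dgat1a (-1.84) and dgat2 (-1.23). The list as a whole did not pass camera (median 0.23, adjusted p = 0.447), while fry gave an adjusted p of 0.0344.

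**Figure D3:**
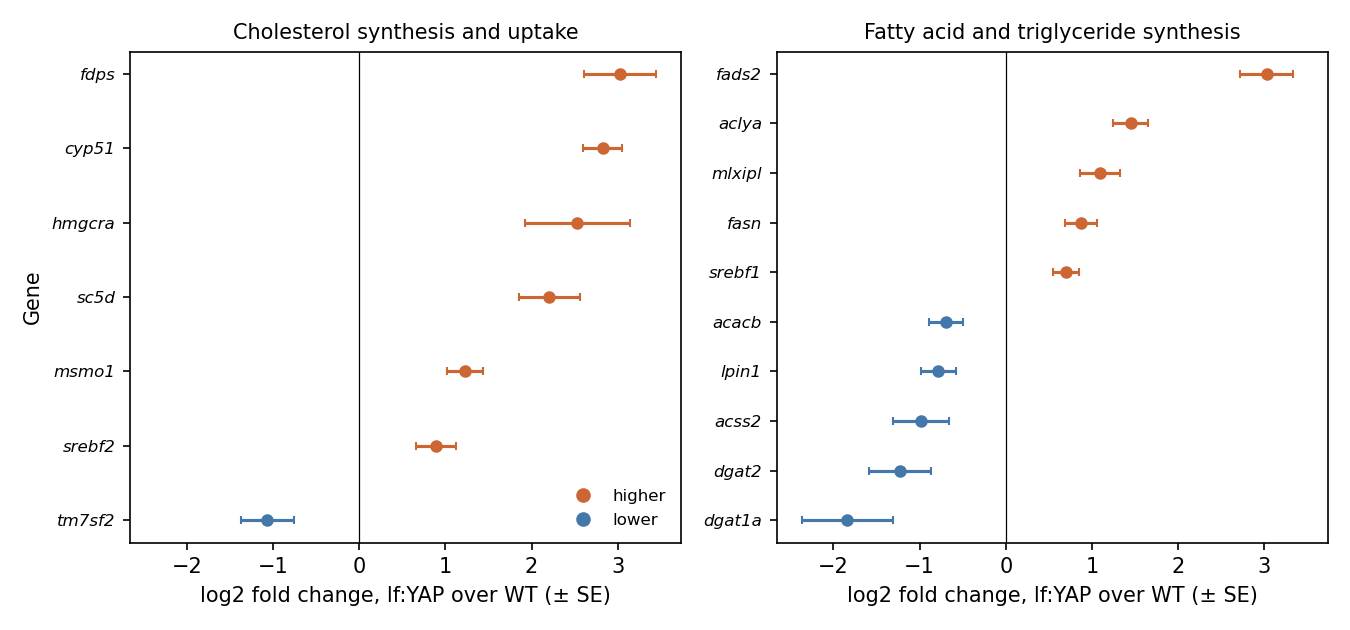
Log2 fold change of lf:YAP over WT (x axis, ± SE) for the genes named in the text (y axis) of cholesterol synthesis and uptake on the left and of fatty acid and triglyceride synthesis on the right, 4 libraries per group (orange higher, blue lower). In the left panel tm7sf2 alone is lower, at -1.06, and in the right panel values run from -1.84 for dgat1a to 3.03 for fads2.

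The sgk1 transcript did not differ detectably between groups. Its level was 612 ± 117 CPM in WT and 694 ± 78.3 CPM in lf:YAP (SD, n = 4 each), a log2 fold change of 0.18 with a 95% interval from -0.26 to 0.62 (adjusted p = 0.513). With total counts alone it was 0.51 (adjusted p = 0.0583). The kinase gene mtor rose from 30.9 ± 2.43 to 46.8 ± 4.61 CPM, a log2 fold change of 0.60 ± 0.15 (SE; adjusted p = 0.0114). Of 32 tested members of the SGK and mTORC1 pathway, 5 rose and 4 fell, with the same counts adjusted over the list alone. With mtor, the higher members were pdpk1b (0.96), which encodes the upstream kinase PDK1, the Rag GTPase gene rragca (from 7.37 to 17.1 CPM), the mTORC2 subunit gene rictorb (1.38) and the translation repressor gene eif4ebp1 (0.55). The lower members were sgk2a (-1.70), the amino acid transporter subunit gene slc3a2b (-1.24), eif4ebp3l (-0.72) and nedd4l (-0.70). The list did not pass camera (adjusted p = 0.907), and its median of 0.01 and mean of -0.07 differ in sign.

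Few cell cycle genes were abundant enough to be tested, and the 4 that were rose in lf:YAP, with the same 4 adjusted over the list alone. The replication clamp gene pcna rose from 3.60 ± 1.01 to 13.6 ± 9.55 CPM (SD, n = 4 each; adjusted p = 0.013), and hmgb2a, mcm7 and ube2c had log2 fold changes of 0.77, 1.48 and 1.02. With 4 members the list was too small for camera. A rare gene could pass a count filter through its level in 1 group alone. For example, mcm7 had 5 to 10 counts per library in WT and 10 to 44 in lf:YAP. The share of tested members that rose may therefore be inflated, here and with the looser filter below. With genes kept at 1 CPM in at least 4 libraries, 15 members were tested and 10 rose, among them the replication helicase genes mcm2, mcm3, mcm4, mcm5 and mcm6, with an adjusted p of 1.51e-05 by camera and an adjusted p of 0.439 with an estimated correlation. Single libraries weighed on these counts: without lf:YAP replicate 4, pcna had a log2 fold change of 1.34 and 1 member passed in place of the 4. The hmgb2a call was also lost without WT replicate 3, the mcm7 call without WT replicate 1, 2 or 3, and the ube2c call without any single library but lf:YAP replicate 2. Under the looser filter 4 passed without lf:YAP replicate 4 and 5 without WT replicate 1 or 2, in place of the 10. There were 6 without WT replicate 3 or 4, 7 without lf:YAP replicate 1 or 2, and 9 without lf:YAP replicate 3.

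Some hepatocyte genes fell and fewer rose, and most did not pass. Of 37 tested members, 3 rose, 11 fell and 23 did not pass, or 3 and 15 adjusted over the list alone. With total counts alone 6 rose and 13 fell, and the median moved from -0.40 to -0.18. The secreted glycoprotein genes fetub, ahsg1 and ahsg2 fell, fetub from 17174 ± 4474 to 5736 ± 2562 CPM (SD, n = 4 each), with log2 fold changes of -2.88 ± 0.55 and -3.12 ± 0.54 (± SE) for ahsg1 and ahsg2. The ahsg1 and ahsg2 values without lf:YAP replicate 3 were -3.50 and -3.71. The liver fatty acid binding protein gene fabp10a rose from 2731 ± 296 to 7991 ± 1431 CPM, a log2 fold change of 1.55 ± 0.20, and the complement gene c3a.2 rose by 1.87 ± 0.27. The list had a median of -0.40 and an adjusted p of 0.00361 by camera, with an adjusted p of 0.739 with an estimated correlation and 0.211 by fry.

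Some markers of bile duct cells and hepatic progenitors rose. Of 15 tested, 6 were higher, 0 were lower and 9 did not pass (7 and 0 adjusted over the list alone). The keratin genes krt18a.1 and krt8 rose from 272 ± 28.5 to 1074 ± 251 CPM and from 766 ± 49.6 to 1599 ± 341 CPM (SD, n = 4 each), the annexin gene anxa4 from 417 ± 44.1 to 1100 ± 428 CPM, and the ductal transcription factor gene sox9b by 1.05 ± 0.26 on the log2 scale (± SE). The list had an adjusted p of 0.00979 by camera and an adjusted p of 0.437 with an estimated correlation. Of 18 tested genes of Notch, Wnt and TGF-beta signalling, 5 rose and 0 fell, also adjusted over the list alone, among them the cyclin D1 gene ccnd1 (1.49 ± 0.21) and the ligand gene tgfb3 (2.25 ± 0.48). The other 3 calls depended on single libraries: id1 was lost without lf:YAP replicate 1 or WT replicate 2 or 3, tgfbr1a without lf:YAP replicate 1 or 2 or WT replicate 2, 3 or 4, and jag1b, also in the biliary list, without lf:YAP replicate 2 or 4 or any WT replicate (adjusted p of 0.054 to 0.116). The tool and model mattered as well: jag1b was lost with DESeq2 (adjusted p = 0.052), limma-voom (0.0664) and the replicate block (0.123), and tgfbr1a with DESeq2 (0.0702). The Notch, Wnt and TGF-beta list had an adjusted p of 0.0198 by camera and an adjusted p of 0.437 with an estimated correlation.

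Some markers of skeletal muscle, intestine and stellate cells were lower in lf:YAP libraries, and most of each list did not pass. Muscle and intestine markers measured other tissue in the dissected samples, so their fall need not be a change within the liver. Their sums were 2226 and 2047.5 CPM in WT replicate 4, and 1544 and 1296 CPM in lf:YAP replicate 3. Within each group these were the highest, in the libraries also richest in exocrine pancreas transcripts. Whether dissection accounts for the fall was not tested. Of 23 tested skeletal muscle markers, 6 fell and 2 rose, the same adjusted over the list alone; myhz1.3, a fast myosin gene, fell by 1.53 ± 0.35 on the log2 scale (± SE), while the actin genes acta1b and acta1a rose by 2.78 ± 0.43 and 2.26 ± 0.52, though acta1a did not pass with limma-voom (adjusted p = 0.095). Of the muscle genes that fell, ttn.2 did not pass without lf:YAP replicate 2 (0.0605), nor myhz1.2 without lf:YAP replicate 1 or 2 or WT replicate 2 or 3 (0.0521 to 0.0579). By fry the muscle and intestine lists had adjusted p-values of 0.211 and 0.223. All muscle markers together took 0.158 ± 0.048% of the counts in WT and 0.082 ± 0.041% in lf:YAP (SD, n = 4 each; 2-sided exact permutation p = 0.0571, adjusted p = 0.286 over 10 library measures). The share of intestine markers did not pass either, at 0.109 ± 0.0591% and 0.0738 ± 0.0253% (SD, n = 4 each; 2-sided exact permutation p = 0.343, adjusted p = 0.571). Of 16 tested intestine markers, 4 fell and 0 rose (5 and 0 adjusted over the list alone), with the chitinase gene chia.1 at -2.74 ± 0.49. The other 3 calls were lost without lf:YAP replicate 2: anpepa (adjusted p = 0.0829), anpepb (0.0765) and slc15a1b (0.055). The anpepa call was also lost without lf:YAP replicate 4 or WT replicate 3 or 4, anpepb without lf:YAP replicate 1 or 3, and slc15a1b without lf:YAP replicate 4. Of 15 stellate and mesenchymal markers, 4 fell and 0 rose, also adjusted over the list alone. The fibronectin gene fn1b, by far the most abundant of them, fell from 5107 ± 556 CPM in WT to 1961 ± 480 CPM (SD, n = 4 each). In WT it made up nearly all of the summed 5276 CPM of the listed markers, while vim, desma and rgs5a stood at 10.9 to 23.5 CPM. Its fall may therefore not be that of stellate cells, and which cells its transcripts came from was not tested. The other 3 calls, vim (adjusted p = 0.108), desma (0.0881) and rgs5a (0.126), were lost without lf:YAP replicate 2, and each also without WT replicate 2 or 4; desma was lost as well without lf:YAP replicate 1 or WT replicate 3, vim without lf:YAP replicate 4, and rgs5a without lf:YAP replicate 1 or 4. By camera the adjusted p was 0.000812 for muscle, 0.0097 for intestine and 0.0373 for stellate markers, with an adjusted p of 0.739 for each with an estimated correlation. The stellate result did not pass without WT replicate 4 (0.185), lf:YAP replicate 2 (0.106) or lf:YAP replicate 4 (0.0877), with the replicate number as a block (0.0557), without the 20 most abundant genes (0.178), with the looser filter (0.128), with no filter (0.104), by fry (0.206) or with an exocrine covariate (0.0566).

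The remaining cell type lists with enough tested members did not pass camera. Of 23 exocrine pancreas markers, 0 rose and 0 fell, also adjusted over the list alone (median -0.08, adjusted p = 0.447), but the list was lower without lf:YAP replicate 3 (adjusted p = 0.00468) and without WT replicate 1 (adjusted p = 0.0198). With an estimated correlation neither passed, at an adjusted p of 0.646 and 0.724, against 0.912 with all libraries. None of 13 endothelial markers passed (0 of 13 adjusted over the list alone; adjusted p = 0.677), nor the only macrophage and leukocyte marker tested, lect2l, at 0.75 ± 0.85. Without lf:YAP replicate 3 lect2l was lower in lf:YAP (-1.02, adjusted p = 0.00257). With more genes kept, the macrophage and leukocyte list was higher by camera: with the looser filter 2 of 13 members rose (adjusted p = 0.0388, and an adjusted p of 0.411 with an estimated correlation), and with no filter 3 of 28 rose (adjusted p = 0.000176, and an adjusted p of 0.26 with an estimated correlation). Under the looser filter it did not pass without WT replicate 1 (0.078) or 3 (0.0901), or without any 1 of the lf:YAP libraries (0.0587 to 0.113). Of 15 skin markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.244), with the envoplakin gene evpla at -1.54 ± 0.36. The other 3 calls were lost without lf:YAP replicate 2, namely pkp3a (adjusted p = 0.0988), col17a1a (0.0807) and cyt1 (0.0975), as they were without lf:YAP replicate 1 or WT replicate 2; pkp3a and cyt1 were also lost without lf:YAP replicate 4 or WT replicate 4, and col17a1a without WT replicate 3. Of 5 erythroid markers, fech (-0.87) and tspo (-0.65) fell, the same adjusted over the list alone, and the tspo call was lost without lf:YAP replicate 2 or 4 or WT replicate 2 or 3, and both calls with total counts alone. In the main comparison the erythroid median of 0.59 had the opposite sign to these falls (adjusted p = 0.937 by camera). There hbae3 (1.32), hbbe2 (0.81) and epb41b (0.59) were higher without passing. Of 3 endocrine pancreas genes the insulin gene ins rose (1.02 ± 0.30), also adjusted over the list alone, a call lost without lf:YAP replicate 2 or WT replicates 1, 3 or 4.

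Other metabolic lists had members in both directions. Of 33 genes of glycolysis, gluconeogenesis and the pentose phosphate pathway, 5 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.252 by camera). The pentose phosphate gene pgd rose by 0.94 ± 0.18 on the log2 scale (± SE), while pgam1a and tkta fell by 1.84 ± 0.21 and 2.19 ± 0.34. Of 26 fatty acid oxidation genes, 3 rose and 7 fell (the same adjusted over the list alone; adjusted p = 0.195), with the mitochondrial gene hadhb at 0.97 ± 0.24 and the peroxisomal gene hsd17b4 at -0.93. Of 22 genes of lipoproteins, lipid droplets and lipolysis, 4 rose and 7 fell (4 and 8 adjusted over the list alone; adjusted p = 0.244). There the sterol acyltransferase gene soat2 fell by 2.42 ± 0.22 while its paralog soat1 rose by 0.80 ± 0.16. The lipid droplet gene cidec had -3.16 ± 0.60, and -4.22 without lf:YAP replicate 3, and lcat, 1 of the 4 that rose, did not pass without WT replicate 1 (0.0535) or 2 (0.0518). Of 20 nucleotide and glutamine genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p = 0.195, or 0.016 by fry), with the glutamine synthetase paralogs glula and glulb at -1.61 ± 0.29 and 1.18 ± 0.23. Among those that fell, shmt2 did not pass without lf:YAP replicate 1 or 2 or WT replicate 1 (0.0545 to 0.0637). Of 9 bile acid genes, 1 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.759), with the phospholipid exporter gene abcb4 at -1.68 ± 0.26. The gene that rose, hsd3b7, did not pass without lf:YAP replicate 1, 2 or 4 or WT replicate 2, 3 or 4 (adjusted p of 0.061 to 0.124).

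Stress and growth lists did not pass camera. Of 18 acute phase and inflammation genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.447), and the fallen ones were the immediate early genes fosab (-3.49 ± 0.41), junba (-1.91 ± 0.28) and junbb (-2.06 ± 0.35) and the C-reactive protein genes crp3 (-1.78 ± 0.25) and crp2 (-1.82 ± 0.36). Of 21 ER stress genes, 0 rose and 3 fell (0 and 2 adjusted over the list alone; adjusted p = 0.677), with the chaperone gene hspa5 at -1.11 ± 0.23; the median of 0.04 and the mean of -0.06 differ in sign. The hyou1 call was lost without any 1 library but lf:YAP replicate 3 (0.0626 to 0.131), and trib3 without lf:YAP replicate 4 or WT replicate 2 or 3 (0.06 to 0.0741). With total counts alone both calls were lost, hyou1 at -0.22 (adjusted p = 0.478) and trib3 at -0.27 (adjusted p = 0.361). Both were also lost with no filter, and hyou1 with the looser filter, DESeq2 and the replicate block. Of 30 ribosome biogenesis genes, nop16 (1.04) rose and mycb (-2.21) fell (0 and 0 adjusted over the list alone; adjusted p = 0.195); the nop16 call was lost without lf:YAP replicate 1 or 3 or WT replicate 1, 2 or 3, and the mycb call without lf:YAP replicate 2 or 4.

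**Figure D4:**
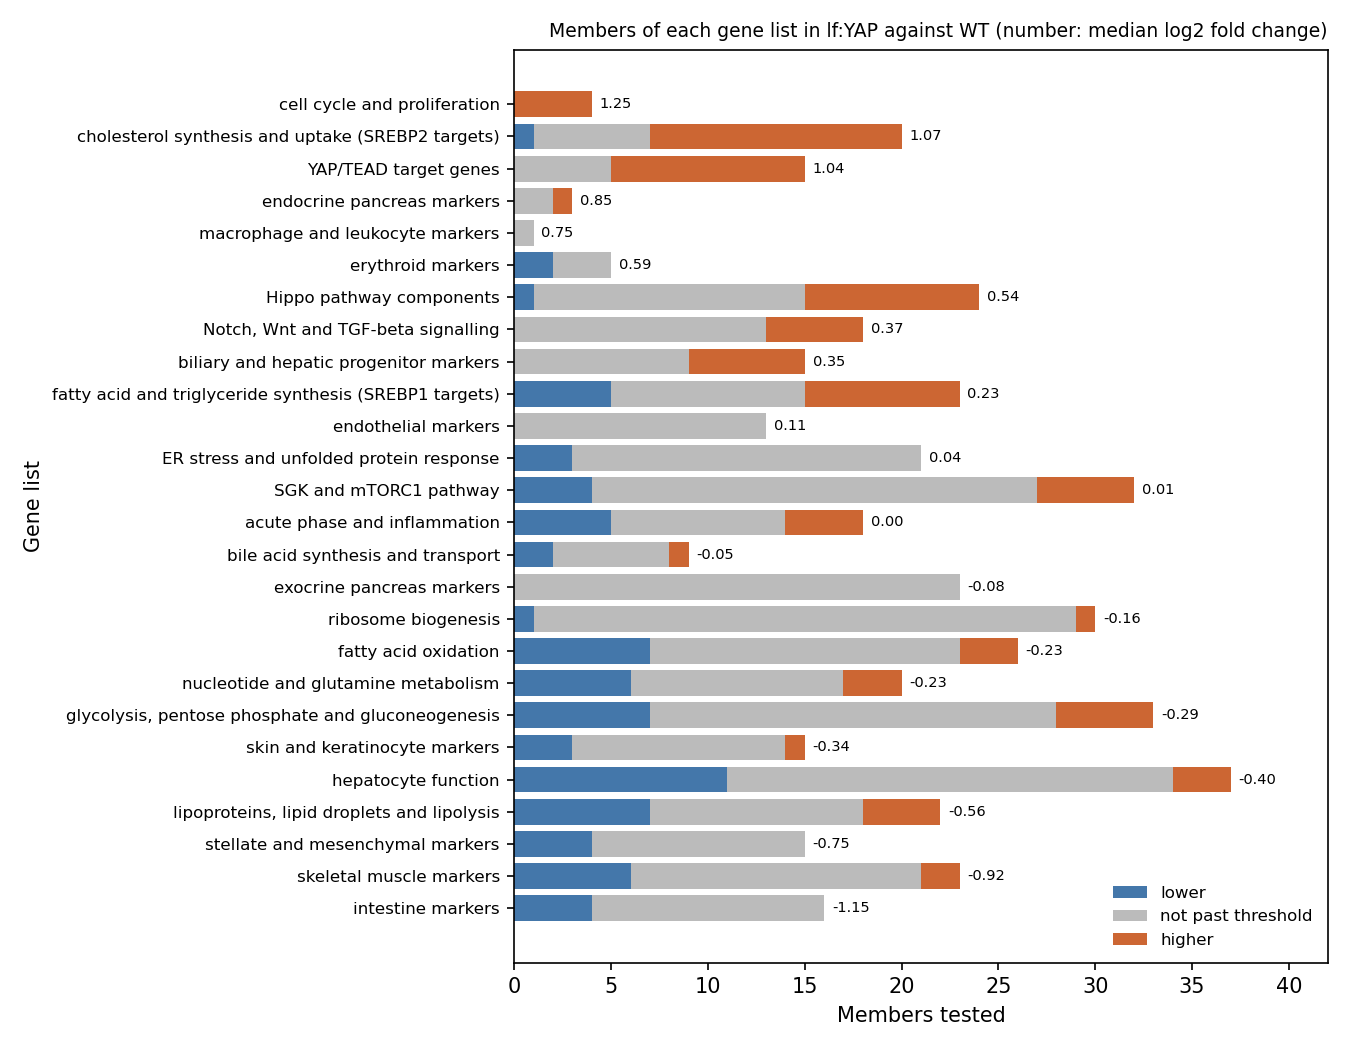
Number of tested members (x axis) of each of the 26 gene lists (y axis) that were lower (blue), not past the threshold (grey) or higher (orange) in lf:YAP, with 4 libraries per group and the median log2 fold change of the list beside each bar. Lists are ordered by that median, from intestine markers at -1.15 to the cell cycle genes at 1.25, of which only 4 were tested.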

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

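All tests in this part were chosen after the result was seen. A library was singled out where its gap to the nearest of its group was large against the range of the group. Chance does this for about 1 in 20 groups of 4. Of 342 groups examined 19 were singled out, against 17.1 by chance if the groups were independent. They came from the same 8 libraries, and several of the values fell in lf:YAP replicate 3 or WT replicate 4. The total therefore does not decide which values need a further reason. In lf:YAP replicate 3, btk (7.32 CPM against 30.9 to 38.0 in the others), nuak2 (21.5 against 65.9 to 81.8) and acta1a (4.31 against 21.4 to 29.0) were low, and lect2l was high (239.5 against at most 26.2). In the same library the mean log2 CPM was high for exocrine pancreas markers (8.48 against 6.10 to 6.33) and low for Notch, Wnt and TGF-beta genes (3.61), and exocrine transcripts were 1.48% of the counts. In lf:YAP replicate 4, chac1 was low at 414 CPM and the biliary and progenitor mean was high at 6.18 log2 CPM. In lf:YAP replicate 1 the single cyp2aa8 count gave 0.363 CPM.

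In WT replicate 4, fetub was low at 10540 CPM, mcm7 was high at 2.78 CPM, prkacba had 0.556 CPM against 0 in the others, the erythroid mean was high at 3.86 log2 CPM, and the total of 3798000 counts stood above the other WT totals. WT replicate 2 had the lowest aclya, 8.49 CPM, and a slc5a9 level of 0. WT replicate 1 had the highest shmt2, 81.1 CPM, and the highest cholesterol list mean of the WT group, 3.65 log2 CPM. Among the rows with no gene name, which no comparison used, 60 of 197 tested were changed between the groups when they were kept in the fit, 30 in each direction.

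The lf:YAP replicate 3 library was nearest to WT, and over 2316 genes called without it, it reached a median of 0.541 of the log2 change of the other lf:YAP libraries. Choosing the genes by their change in those other libraries favours a low share. The share was not computed for any other library, so it has no value to be set against. WT livers mixed into that pool would need a WT share of 0.543 to account for its yap1 level. This assumes that its lf:YAP livers had the yap1 level of the lowest other lf:YAP library, 639 CPM. But 110 genes that fell at least 4-fold in the other libraries stood at a median WT share of 0.252 (quartiles 0.117 and 0.496). Under that assumption this argues against such a mixture as the whole cause, while lf:YAP livers with less yap1 would need a smaller WT share. Dilution by RNA of other tissue, as the whole cause of its low yap1, is argued against by hepatocyte genes. They stood at a median of 1.61 times the other lf:YAP libraries (quartiles 1.25 and 1.92) where yap1 stood at 0.305. Some dilution stays open, as its exocrine pancreas markers summed to 17234 CPM against at most 3962 CPM in the other lf:YAP libraries. Lower YAP activity in that pool stays open. The library was the lowest of the lf:YAP group in 10 of 12 YAP/TEAD targets called without it, and in 68.4% of the 1100 other genes called higher without it. This comparison cannot decide, because lower YAP activity could lower both sets and both were chosen without this library. Other differences between the larvae were not tested.

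The rise of fabp10a could in principle come from transgene reads, if the transgene carried fabp10a sequence, which the labels do not say. Reads of a single transgene transcript would keep the extra fabp10a level in 1 ratio to the extra yap1 level, but that ratio ran from 3.94 to 16.0 across the lf:YAP libraries, a spread of 4.07 times, where the WT coefficient of variation of fabp10a was 10.8%. With the endogenous level scaled by each library's median hepatocyte gene the spread was 3.42 times. This argues against transgene reads as the whole cause; a part from them, and an effect of YAP on the fabp10a gene, stay open and untested.

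The fall of the hepatocyte list may reflect either fewer hepatocyte transcripts overall or changes of particular genes. A smaller share of hepatocyte RNA as the whole cause would lower all abundant hepatocyte genes by 1 common amount, so that about 1.55 of the 31 abundant members other than fabp10a would have a 95% interval that leaves out their median, -0.42 on the log2 scale. In fact 10 did, 6 above and 4 below, with ambp (0.07, from -0.38 to 0.52) among those above and ahsg1 (-2.88) among those below, which argues against it as the whole cause. The scaling between libraries stays open for the list as a whole: with total counts alone the median of all 37 tested members was -0.18 in place of -0.40, with quartiles of -0.76 and 0.22 on both sides of 0. A smaller fall of hepatocyte RNA alongside gene-specific changes, and an effect of YAP activation on particular hepatocyte genes, remain open as hypotheses.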

How the results depend on the processing

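The alternatives added after the data had been seen were the fit with unnamed rows, the fit without the 2 libraries richest in pancreatic counts, the exocrine covariate, and, for the macrophage and exocrine lists, estimated correlations and left-out libraries beyond those first chosen. No gene called changed had the opposite sign in any fit. The count of 1804 changed genes was 1789 to 2117 under RLE or upper quartile factors, removal of the 20 most abundant genes, the looser filter, DESeq2 (1906), limma-voom (1866) or unnamed rows, 1775 with marker genes left out, 2028 with the exocrine covariate and 2336 without the pancreas-rich libraries. It was 2855 (1410 higher, 1445 lower) with no filter, where more genes were tested, 880 (497 and 383) at an adjusted p under 0.01, and 666 (383 and 283) against a 1.5-fold change. With total counts alone 1537 rose and 517 fell, as that scaling moves all genes up. Leaving out 1 library gave 1308 to 2537 changed genes, 705 to 1225 higher and 603 to 1312 lower, and a yap1 log2 fold change of 4.94 to 5.53. The replicate numbers did not pair the libraries: same-numbered libraries had correlations of -0.01, 0.01, 0.07 and -0.05 in their deviations from the group means, and 1 of 4 WT libraries correlated best with its own number. With the replicate block 1685 genes were changed (855 higher, 830 lower), 1565 of them also changed without it in the same direction.

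The number of cell cycle members that rose, 4 in the main comparison, was 14 with no filter, 10 with the looser filter and 7 with DESeq2, where more members were tested, 2 with limma-voom, and 1 to 6 on leaving out 1 library; the cause of the limma-voom value was not tested. With an estimated correlation the YAP/TEAD and cholesterol lists both had an adjusted p of 0.437, and leaving out 1 library gave 7.87e-06 to 0.000397 and 7.87e-06 to 0.000171. The fatty acid list passed with fry (0.0344) and not on leaving out 1 library (0.495 to 0.793). The SGK and mTORC1 list, never past the threshold, turned from lower to higher with the looser filter (0.758), fry (0.907) and no filter (0.549), and on leaving out lf:YAP replicate 4 (0.900; range 0.617 to 0.974).

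Other reversals were among results that did not pass in the main comparison. Of these, lect2l passed the quasi-likelihood test in the reversed direction without lf:YAP replicate 3 (adjusted p = 0.00257). It also did so without the pancreas-rich libraries (adjusted p = 0.00527). On leaving out 1 library, log2 fold changes ran from -0.51 to 1.22 for cela1.4, -0.53 to 0.99 for cpa1, -1.02 to 1.07 for lect2l and -1.27 to 0.17 for pdia2, and adjusted p-values from 0.600 to 0.974 for bile acid, 0.353 to 0.900 for endothelial, 0.354 to 0.983 for ER stress, 0.624 to 0.997 for erythroid and 0.00468 to 0.900 for exocrine genes. lect2l was at -0.17 with limma-voom, -0.18 with the block and -0.82 without the pancreas-rich libraries, where cpa1 was at -0.042; the erythroid list turned with fry (0.907) and limma-voom (0.871), and ER stress with no filter (0.945). Causes were not tested. Of 112 named genes that passed, 82 also passed under every change of scaling, filter, tool, model or libraries at the same threshold of 0.05, and the stricter threshold and the test against a 1.5-fold change were applied to the counts of genes only; 27 lost the call on leaving out at least 1 library. Over all results and alternatives, 2945 values stayed on their side of the threshold, 175 lost it, 40 gained it, 24 reversed and 16 counts moved by over 1.5 times.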

Other observations

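Families of genes that share a symbol stem were examined after the data had been seen, 82 families in all. Glucuronosyltransferase genes, which conjugate bilirubin, hormones and foreign compounds, were lower in lf:YAP: 7 of 11 tested fell and 0 rose, with a median log2 fold change of -1.20 and a camera adjusted p of 0.00116, but an adjusted p of 0.930 with an estimated correlation. Examples are ugt5b4 (-2.60 ± 0.33, SE), ugt1b5 (-2.27 ± 0.43) and ugt2a4 (-1.78 ± 0.31). Cytochrome P450 genes fell in 12 of 37 cases and rose in 1, cyp51 of the cholesterol list (median -0.27, adjusted p = 0.0292, and 0.968 with an estimated correlation), with cyp2p8 at -3.18 ± 0.63 and cyp2aa12 at -1.44 ± 0.23. Solute carrier genes fell in 39 of 164 cases and rose in 13 (adjusted p = 0.0197, and 0.930 with an estimated correlation), and rab genes of vesicle traffic and their partners rose in 7 of 41 and fell in 0 (adjusted p = 0.0496, and 0.930 with an estimated correlation), with rab7b at 2.38 ± 0.33. Several of these genes are close paralogs, whose reads cannot always be told apart.

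Summed over all listed members, most of them too rare to be tested singly, cell cycle transcripts took 44.4 ± 2.50 CPM in WT and 125 ± 70.3 CPM in lf:YAP (SD, n = 4 each; 2-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.0743 adjusted over the 26 lists), and each lf:YAP library lay above each WT library. Macrophage and leukocyte markers took 63.6 ± 15.3 and 118 ± 102 CPM (exact permutation p = 0.343, adjusted p = 0.446). The lf:YAP mean rested on replicate 3, at 269 CPM, and was 67.5 CPM without it. Most of the replicate 3 sum was lect2l alone, at 239.5 CPM, as was most of the WT sum, at 44.4 CPM. In the other lf:YAP libraries lect2l had at most 26.2 CPM, of sums of 54.3 to 82.1 CPM. The sums therefore do not decide on the other members, whose sum without lect2l was not tested. Fatty acid and triglyceride synthesis genes, 8 of which rose, summed to less in lf:YAP, 1913 ± 233 against 2660 ± 315 CPM (exact permutation p = 0.0286, adjusted p = 0.0743). These sums were chosen after the data had been seen.

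Other splits of the 8 libraries into 4 and 4 were fitted in the same way, 35 in all with the real one. The real split called 1804 genes and the highest of the others called 0, which argues against chance for the number of changed genes. That is 1 of 35 splits, the smallest share that 4 against 4 can give. For the number of lists passing camera, chance cannot be excluded: the real split called 9, 8 of 35 splits called as many, and the highest other called 14. The YAP/TEAD target list had a camera adjusted p of 0.000121 in the real split and 4.66e-05 in the lowest other, so 2 of 35 splits were as extreme. That other split set WT replicates 1, 3 and 4 with lf:YAP replicate 3 against the rest. It kept most of the real grouping, so the splits do not decide on chance for this list, while 10 of its members passed singly. For the cholesterol list the camera adjusted p was 7.26e-05 in the real split and 0.000472 in the lowest other (1 of 35, again the smallest share). Of its 20 tested members, 13 passed singly. That share is not corrected for the number of lists, and the list's adjusted p was 0.437 by camera with an estimated correlation, so chance is not excluded for the list.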
